A study of Brassica rapa with 6 samples.

How the data were processed

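RNA was measured in 6 libraries of baby Chinese cabbage (*Brassica rapa*), 3 of leaf and 3 of petiole. Per the labels' protocols, total RNA was isolated with Trizol, ribosomal RNA was removed and strand-specific libraries were built. Small RNA libraries and circular RNAs were not analysed here. The labels number the libraries 1 to 3 in each tissue without saying whether they came from separate plants, so p-values measure the spread between these samples, which may be technical.

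The deposited table held 49200 loci on 10 chromosomes (A01 to A10) with an estimated count and an FPKM value per library, per the file headers. Of these loci 30985 had an identifier of a StringTie transcript assembly, 46357 carried at least 1 annotated gene name, 691 merged several annotated genes and 2843 had no gene name. Loci without a gene name took 5.32% ± 0.12 of the counts in leaf and 6.36% ± 0.37 in petiole (SD, n = 3 each) and stayed in library sizes and tests. The aligner, the counter and the plant genome build are not given in the sources used here. The submitters' processing notes list Bowtie 0.12.2 and mm8, which is a mouse build, without saying what either was used for. Coordinates are those of the deposited table. The reference gene table at hand shared no identifiers with it and was not used here.

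The deposited estimated counts were whole numbers but not a tally of reads. Low values piled up at multiples of about 3.78 units (3.71 to 3.78 over the libraries), as when coverage is converted to counts with a fixed read length. They were not normalised. The floor of a locus was set at 3 fragments, or 12 units, per library. Where all libraries of a tissue were at 0, the fold is given as a bound against that floor and covers counting error only. The deposited FPKM, fragments scaled to transcript length and library depth, were proportional to the counts within each locus, with a denominator per library that was larger than the sum of the counts. A value of 0.0001 stood where the count was 0. The size of this denominator was estimated by taking the loci with the most units per FPKM and base of span as unspliced. CPM are counts per library size after TMM scaling.

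The comparison of petiole with leaf used edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the estimated counts, which already were whole numbers, so that rounding changed nothing. Loci were kept by filterByExpr, libraries were scaled by TMM factors (0.885 to 0.925 in leaf, 1.095 to 1.137 in petiole), and the model held tissue alone with robust fitting. Tests were two-sided, with Benjamini-Hochberg adjustment over all loci tested and a threshold of 0.05. The biological coefficient of variation was 26.5%. The plan made before the data were examined set limma on log2(FPKM + 1) as the main test unless the table held counts, in which case edgeR was the main test and limma an alternative. Since a count unit was worth less than a fragment, the test was also run on counts divided by 3.78. On simulated counts for 31473 loci, 200 loci were changed, all drawn from loci above a minimum mean in leaf. There edgeR recovered 32.8% of the loci changed 1.5-fold, 56.7% of those changed 2-fold and 86.4% of those changed 4-fold, with 6 false calls. Far fewer loci were changed than differed in the data, and low loci were not among them. These shares are therefore not the power of the real test.

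Gene lists, 43 in all, were fixed before the data were examined and matched by the descriptions in the table, since it gives no gene symbols. The search text of the LSH list also matched 11 dehalogenases among its 33 hits. These were removed after a first test of the list as matched had been seen, because they belong to another family, and as matched the list also passed (29 loci tested, camera adjusted p = 0.0032). Lists were tested with camera from limma 3.58.1, with a preset correlation of 0.01 and beside it an estimated correlation, and with fry, which asks whether a list's loci move on balance one way. With camera 22 lists passed, 15 higher in petiole and 7 higher in leaf. With an estimated correlation 12 passed and with fry 40. Over the list alone, counts matched those over all loci for 24 lists and differed by at most 6 loci for the other 19.

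Named loci were chosen by a rule set before the data were examined. They are, per list, up to 3 loci with the largest change past the threshold and a mean FPKM of at least 5 in the higher tissue. Added to these were the 10 described loci with the largest change in each direction at a mean FPKM of at least 10 and no overlap between the libraries of the tissues, which chance gives for 10% of loci. All LSH, NPR5, NPR6, TCP15 and MOR1 loci and the 3 loci with the highest FPKM in each tissue were also included. Of the 172 loci chosen, 18 overlapped another locus, and the counting is not stated to use strand. Among those printed, MSTRG.26531, MSTRG.5739, BraA03g012220.3C and BraA01g035500.3C are such loci, and so are the 3 most abundant ones. Loci of gene families in this polyploid-derived genome can share reads with near-identical copies, and their split between copies is uncertain.

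Alternatives were limma on log2(FPKM + 1), with pseudocounts of 0.1 and 0.5, with no filter or a mean FPKM of at least 5 in place of at least 0.5, with FPKM rescaled to a common total, by median-of-ratios factors or by quantiles, and without trend or robust fitting. Fold changes from limma are on the log2(value + pseudocount) scale and understate the change of low loci. Others were DESeq2 1.42.0, no filter on low counts, DESeq2 size factors in edgeR, the replicate number as a block, and each library left out in turn. Chosen after seeing the data were the counts divided by 3.78, overlapping loci summed (at least 80% of both spans shared), the run without the plastid-like region of chromosome A06 and merged loci, the FPKM with the sum of the table as denominator, and the LSH list as matched. KEGG pathways, as the table assigns them, were tested for enrichment with a one-sided hypergeometric test in scipy 1.17.1 over 13850 tested loci with an assignment, for pathways of at least 10 loci. Figures were drawn with matplotlib 3.10.9.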

Results

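The data were RNA sequencing values from 6 libraries of baby Chinese cabbage, a small heading form of *Brassica rapa*, made from plants of an inbred line sampled at maturity with no treatment. There were 3 libraries of leaf and 3 of petiole, the stalk that carries the leaf blade. The deposited estimated counts summed to between 111518411 and 121161682 units per leaf library and between 120805715 and 132861243 units per petiole library. A sequenced fragment added about 3.78 units to these counts, so the totals overstate the number of fragments by that factor. The single comparison of the design asked which genes were expressed differently between leaf and petiole. Levels below are counts scaled to TMM-normalised library size (CPM) as mean ± SD with n = 3 per tissue, and log2 fold changes are petiole minus leaf with their standard error (SE).

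Most photosynthesis loci tested were higher in leaf, and most loci of the arabinogalactan protein, cell cycle and jasmonate lists were higher in petiole. BraA02g005650.3C, annotated as the chloroplast beta carbonic anhydrase 2 that interconverts carbon dioxide and bicarbonate, stood at 513.9 ± 28.0 CPM in leaf and 0.232 ± 0.0731 CPM in petiole. A pectinesterase locus, BraA10g031400.3C, had no counts in any leaf library and 62.2 ± 1.89 CPM in petiole, which made it at least 540-fold higher in petiole. Transcription factors of the LSH (ALOG) family, whose members mark organ boundaries in other plants, were higher in petiole for 16 of 19 loci tested. TCP factors, a family known for control of leaf growth, were higher in leaf for 24 of 35. Both of these lists passed the camera test but had an adjusted p = 0.068 with an estimated correlation.

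Of 31473 loci tested with edgeR's quasi-likelihood test, 19711 (62.6%) differed between the tissues at a Benjamini-Hochberg adjusted p under 0.05. Of these, 9909 were higher in petiole and 9802 were higher in leaf, and 10852 differed at least 2-fold (5400 higher in petiole, 5452 higher in leaf). The median log2 fold change over all loci was 0.01 on this scale. With limma on the deposited FPKM the median of all loci was 0.56, and the split was 17271 higher in petiole against 4485 higher in leaf, or 79.4% of the loci that differed against 50.3% with the counts. Directions below are therefore relative to the middle of all loci, and 1616 loci that differed on the counts also differed on the deposited FPKM with the opposite sign. Log2 CPM of libraries of the same tissue correlated across loci at r between 0.958 and 0.962, and those of different tissues at r between 0.772 and 0.779, where loci are not independent replicates. The first principal component held 78.9% of the variance and separated the tissues.

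**Figure D1:**
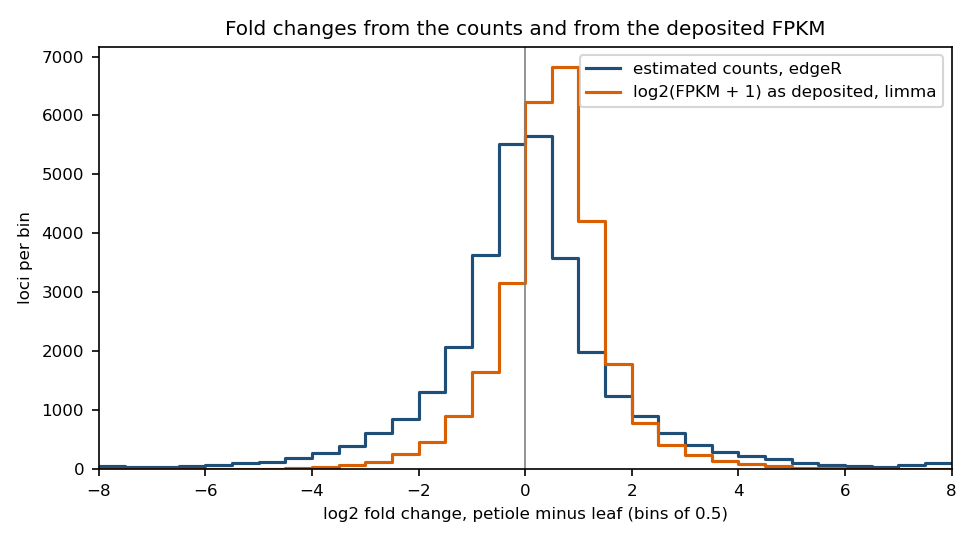
Number of loci (y axis) per bin of the log2 fold change, petiole minus leaf (x axis), from the estimated counts with edgeR (blue) and from the FPKM as deposited with limma (orange). The blue curve is centred near the median of 0.01 and the orange curve lies to the right of it, with a median of 0.56.

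All 23 Calvin cycle loci tested were higher in leaf, with a list median log2 fold change of -3.44, and so were 71 of 76 light harvesting and photosystem loci (1 higher in petiole, median -3.20). Chloroplast ribosomal proteins were higher in leaf for 65 of 71 loci (2 higher in petiole, median -2.34), chlorophyll biosynthesis genes for 30 of 34 (1 higher in petiole, median -1.85) and photorespiration genes for 20 of 29 (4 higher in petiole, median -2.09). BraA08g028350.3C, a chlorophyll a-b binding protein of the light harvesting antenna, stood at 15.4 ± 1.48 CPM in leaf and had no counts in petiole, at least 182-fold lower there. The photosystem II 22 kDa protein locus BraA08g005880.3C, whose product dissipates excess light energy, went from 34.3 ± 2.96 CPM in leaf to 0.0474 ± 0.082 CPM in petiole. BraA03g042340.3C, a serine-glyoxylate aminotransferase of the photorespiratory cycle, stood at 389.5 ± 4.0 CPM in leaf and 1.69 ± 0.481 CPM in petiole, a log2 fold change of -7.85 ± 0.246 (SE) with an edgeR adjusted p of 3.99e-06. BraA08g035300.3C, a protochlorophyllide reductase, had 21.9 ± 1.12 CPM in leaf and 1.55 ± 0.119 CPM in petiole. The camera test, which compares a list with all other loci, gave adjusted p values between 4.46e-23 (light harvesting and photosystems) and 1.4e-05 (photorespiration) for these 5 lists, and each list also passed with an estimated correlation (adjusted p between 0.013 and 0.038). Adjusted over the list alone, light harvesting gave 72 loci higher in leaf, photorespiration gave 21, and chlorophyll biosynthesis gave 2 higher in petiole, with the other counts as above.

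Among the 10 described loci with the largest change toward leaf were also BraA05g040570.3C, the beta carbonic anhydrase 1 (326.8 ± 6.53 CPM in leaf, 0.236 ± 0.0511 CPM in petiole), and BraA01g035500.3C, a phylloplanin-like gene of a family secreted onto the leaf surface (808.0 ± 55.4 CPM in leaf, 0.365 ± 0.0993 CPM in petiole). Sugar transporter genes were higher in leaf for 36 of 58 loci and higher in petiole for 14 (median -0.67, camera adjusted p = 0.0102, adjusted p = 0.068 with an estimated correlation). On the deposited FPKM the median of this list was 0.02, below the 0.56 of all loci. BraA06g018300.3C, annotated as SWEET11, an exporter of sucrose ahead of phloem loading, had 140.5 ± 5.06 CPM in leaf and 9.22 ± 0.307 CPM in petiole. BraA07g014520.3C, annotated as SUC2, which loads sucrose into the phloem, had 92.5 ± 3.44 CPM in leaf and 20.5 ± 1.1 CPM in petiole. The phloem marker list as a whole held 10 loci higher in leaf and 5 higher in petiole of 21 and did not pass (camera adjusted p = 0.135). For sugar transporters, 15 were higher in petiole when adjusted over the list alone, and the other counts were as above.

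Lists of cell wall and cytoskeleton genes differed in how far they passed. All 10 cellulose synthase catalytic subunit loci were higher in petiole (median 1.48, camera adjusted p = 4.39e-05, adjusted p = 0.18 with an estimated correlation). CESA3, a subunit of primary wall synthesis (BraA03g002020.3C, chromosome A03, 910365 to 915133), had 148.3 ± 4.74 CPM in leaf and 609.7 ± 4.5 CPM in petiole, and CESA8, a subunit of secondary wall synthesis (BraA03g048470.3C), had 7.03 ± 1.61 and 22.9 ± 3.78 CPM. Expansins, which loosen the wall during growth, were higher in petiole for 25 of 33 loci and higher in leaf for 6 (median 1.72, camera adjusted p = 0.0006, adjusted p = 0.048 with an estimated correlation). The expansin-A5 locus BraA06g036610.3C had no counts in leaf and 10.6 ± 1.11 CPM in petiole, at least 91.6-fold higher, and the expansin-A3 locus BraA05g007910.3C had 2.81 ± 0.487 CPM in leaf and 59.5 ± 0.562 CPM in petiole. Xyloglucan endotransglucosylase/hydrolases, which cut and rejoin wall xyloglucan, divided into 17 loci higher in petiole and 9 higher in leaf of 33 and did not pass as a list (median 0.71, camera adjusted p = 0.117). The most abundant of those named, BraA03g042150.3C (chromosome A03, 21153222 to 21154979), stood at 137.9 ± 6.4 CPM in leaf and 2229 ± 76.3 CPM in petiole, a log2 fold change of 4.01 ± 0.049 (SE) with an edgeR adjusted p of 3.72e-12. Tubulins and microtubule-associated proteins were higher in petiole for 41 of 61 loci and higher in leaf for 9 (median 0.99, camera adjusted p = 2.39e-05, adjusted p = 0.094 with an estimated correlation). The tubulin beta-1 chain locus BraA07g039280.3C had 171.3 ± 7.62 CPM in leaf and 1742 ± 54.3 CPM in petiole. Both loci annotated as MOR1-like, a protein that organises microtubules, were higher in petiole by small amounts, with log2 fold changes of 0.76 ± 0.039 (SE) for BraA03g018520.3C (edgeR adjusted p = 4.93e-08) and 0.19 ± 0.046 (SE) for BraA05g009570.3C (edgeR adjusted p = 0.00486). The series text names the xyloglucan, expansin, cellulose synthase and MOR1 genes from these samples, so their counts are not independent evidence of direction. With p adjusted over the list alone, 10 tubulin list loci were higher in leaf, and the other counts were as above. On the deposited FPKM the expansin list no longer passed (camera adjusted p = 0.061, and between 0.00028 and 0.096 over all alternatives).

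Arabinogalactan proteins, glycoproteins of the cell surface, were higher in petiole for 40 of 52 loci and higher in leaf for 3 (median 1.53, camera adjusted p = 5.12e-10, adjusted p = 0.015 with an estimated correlation), with the arabinogalactan protein 31 locus MSTRG.26531 at 9.96 ± 2.85 CPM in leaf and 299.6 ± 27.2 CPM in petiole. Pectin-modifying enzymes, a list that also holds inhibitors of these enzymes, were higher in petiole for 76 of 131 loci and higher in leaf for 21 (median 0.93, camera adjusted p = 4.37e-05, adjusted p = 0.043 with an estimated correlation). A polygalacturonase inhibitor of that list, MSTRG.6191, had 1.06 ± 0.17 CPM in leaf and 119.2 ± 11.5 CPM in petiole. The pectinesterase locus BraA01g037360.3C went the other way, with 61.0 ± 2.92 CPM in leaf and 0.738 ± 0.0479 CPM in petiole. Lignin and phenylpropanoid enzymes were higher in petiole for 47 of 84 loci and higher in leaf for 17 (median 0.97, camera adjusted p = 0.00137, adjusted p = 0.043 with an estimated correlation). The cinnamoyl-CoA reductase-like locus BraA02g005610.3C had 1.91 ± 0.644 CPM in leaf and 136.2 ± 4.38 CPM in petiole. Xylem and secondary wall markers were higher in petiole for 11 of 18 loci and higher in leaf for 0 (median 0.56, or 0.46 with loci absent from a tissue set at their bound, camera adjusted p = 0.00775, adjusted p = 0.2 with an estimated correlation). This list did not pass on the deposited FPKM (camera adjusted p = 0.062, and between 0.003 and 0.3 over all alternatives). The lignin list was lost with limma without a filter (camera adjusted p = 0.057) and at a mean FPKM of at least 5 (0.078). Aquaporins, the water channels, were higher in petiole for 27 of 38 loci and higher in leaf for 7 (median 0.72, camera adjusted p = 0.000297, adjusted p = 0.11 with an estimated correlation). The aquaporin locus BraA03g019370.3C, annotated PIP2-2-like, had 7.49 ± 0.681 CPM in leaf and 130.5 ± 7.7 CPM in petiole. Adjusted over the list alone, the counts were 41 loci higher in petiole for arabinogalactan proteins, 78 and 22 higher in petiole and leaf for the pectin list and 49 higher in petiole for the lignin list, with the others as above.

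**Figure D2:**
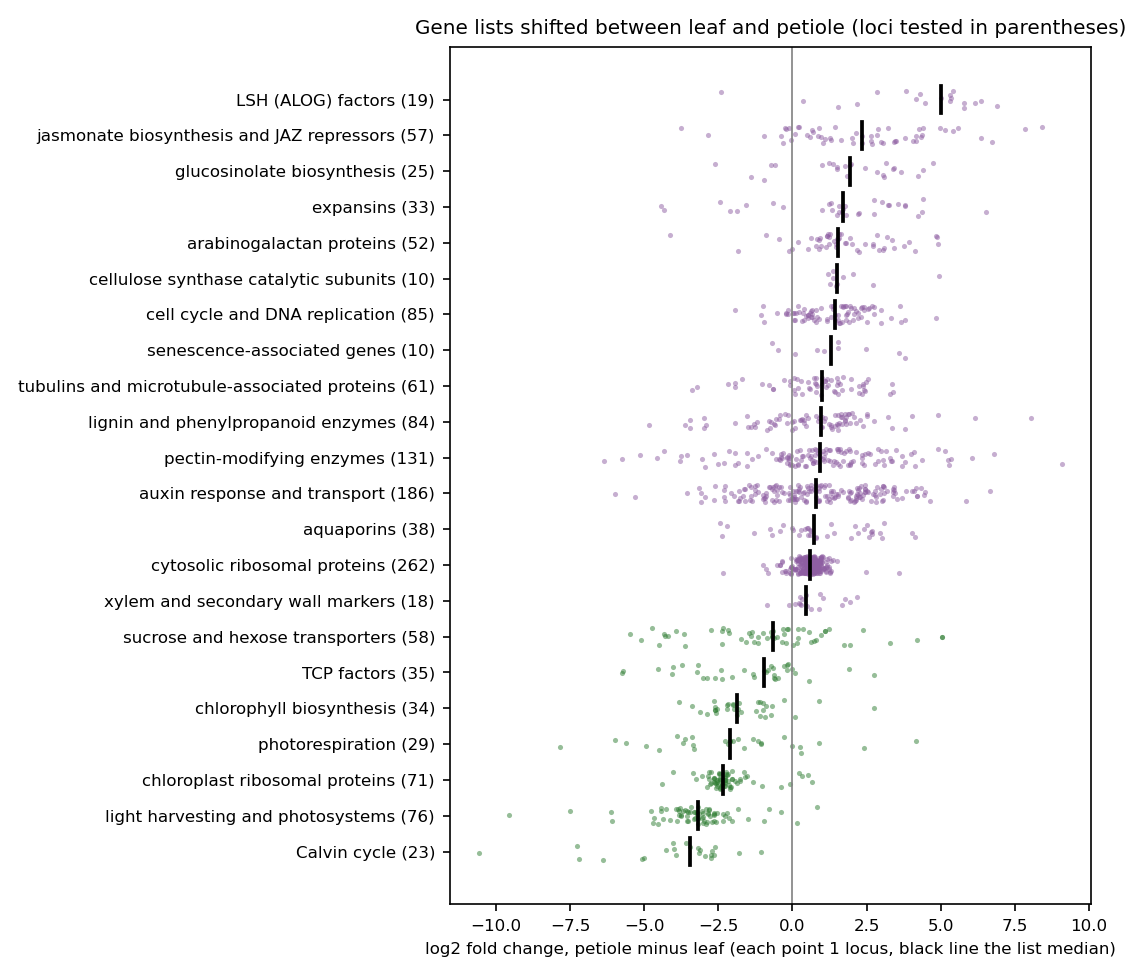
Log2 fold change, petiole minus leaf (x axis), of every locus tested in the 22 gene lists that passed the camera test (rows, with the number of loci tested). Each point is a locus, placed at its lower bound where a tissue had no counts, the black line is the list median, and the 7 lists higher in leaf (green) lie below the 15 lists higher in petiole (purple).

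LSH loci had a list median of 5.02, with 16 of 19 higher in petiole, 1 higher in leaf and 2 not passing (camera adjusted p = 6.14e-05, adjusted p = 0.068 with an estimated correlation). The LSH2 locus BraA05g042610.3C (chromosome A05, 28460877 to 28461470) had 0.216 ± 0.12 CPM in leaf and 15.5 ± 0.936 CPM in petiole, a log2 fold change of 6.15 ± 0.296 (SE) with an edgeR adjusted p of 7.59e-08. The LSH10 locus BraA04g029960.3C reached the highest level of the family in petiole, at 26.8 ± 1.66 CPM against 0.671 ± 0.118 CPM in leaf. The exception was the LSH6-like locus MSTRG.28438, with 13.7 ± 0.937 CPM in leaf and 2.60 ± 0.2 CPM in petiole. Of the loci annotated as LSH3, BraA05g013380.3C did not pass (edgeR adjusted p = 0.657) and MSTRG.11866 was higher in petiole, at 3.26 ± 0.484 CPM against 0.730 ± 0.253 CPM. Of those annotated as LSH7-like, BraA07g026540.3C did not pass (edgeR adjusted p = 0.499) and MSTRG.4764 was higher in petiole, at 2.67 ± 0.629 CPM against 0.366 ± 0.0509 CPM. The 4 loci annotated as NPR5 or NPR6, the relatives of the Arabidopsis BLADE-ON-PETIOLE genes, were all higher in petiole. BraA09g047810.3C, annotated as NPR6, had no counts in leaf and 4.72 ± 1.12 CPM in petiole, at least 40.9-fold higher, and the NPR5 locus BraA05g002190.3C had no counts in leaf and 1.64 ± 0.108 CPM in petiole, at least 14.2-fold higher. With KNOX genes added, the list of organ-base regulators had 6 loci higher in petiole and 3 higher in leaf of 10 (median 3.10, or 1.03 with loci absent from leaf set at their bound) and did not pass (camera adjusted p = 0.171). The KNAT3-type locus MSTRG.5739 was one of those higher in leaf, at 29.0 ± 1.79 CPM against 6.43 ± 0.155 CPM. The series text names LSH genes from these samples, so the LSH count is not independent evidence. Among LSH loci with a mean FPKM of at least 5, limma on the deposited FPKM no longer passed the list (camera adjusted p = 0.22). Most of the 19 loci lay below that limit. The few left for this test included the LSH6-like exception beside loci higher in petiole.

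**Figure D3:**
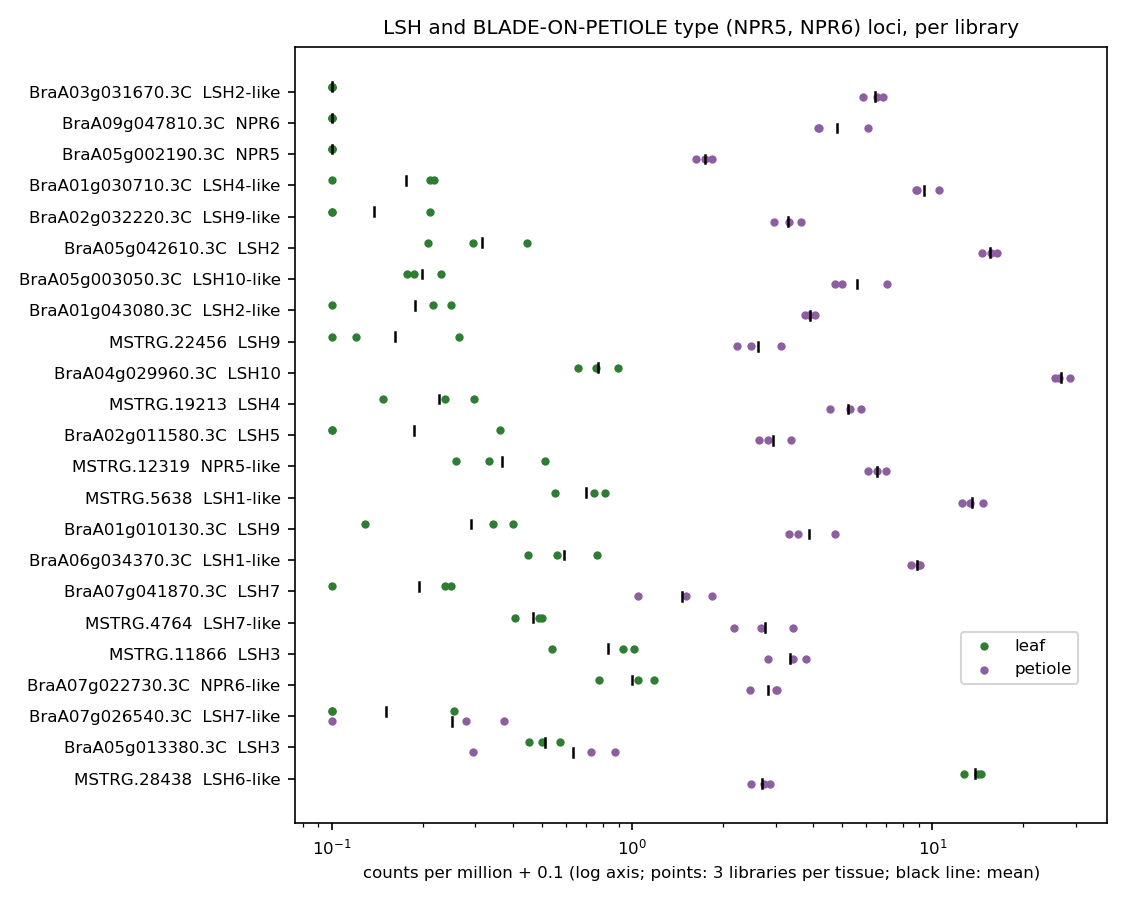
CPM plus 0.1 (x axis, log scale) of each tested LSH and NPR5 or NPR6 locus (rows) in the 3 leaf libraries (green points) and the 3 petiole libraries (purple points), with the mean of each tissue as a black line. Petiole points lie to the right of leaf points in all rows except the LSH6-like locus MSTRG.28438 and the loci BraA05g013380.3C and BraA07g026540.3C, which did not pass the test.

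TCP factors were higher in leaf for 24 of 35 loci and higher in petiole for 3 (median -0.97, camera adjusted p = 6.14e-05, adjusted p = 0.068 with an estimated correlation). On the deposited FPKM the TCP median was -0.07, and 0.09 at a mean FPKM of at least 5, both below the median of all loci there (0.56 and 0.73). The TCP4 locus BraA05g032060.3C, of the class that limits cell proliferation in leaf margins, had 40.01 ± 3.02 CPM in leaf and 2.42 ± 0.396 CPM in petiole, and the TCP13 locus MSTRG.15290 had 13.1 ± 2.27 and 0.562 ± 0.304 CPM. The 3 loci annotated as TCP15-like went the other way. BraA07g034590.3C had 2.66 ± 0.408 CPM in leaf and 18.1 ± 1.3 CPM in petiole, with a log2 fold change of 2.76 ± 0.138 (SE), and the others had log2 fold changes of 1.91 ± 0.153 (SE, BraA07g030260.3C) and 0.55 ± 0.112 (SE, MSTRG.4394). Basic helix-loop-helix (bHLH) factors divided into 40 higher in petiole and 35 higher in leaf of 108 (median 0.16, camera adjusted p = 0.423). At the ends of that list, the bHLH92 locus BraA06g043630.3C had 0.0229 ± 0.0397 CPM in leaf and 27.9 ± 3.21 CPM in petiole, and the bHLH57 locus MSTRG.24110 had 13.3 ± 1.07 CPM in leaf and no counts in petiole, at least 158-fold lower there. LOB domain factors had 11 loci higher in petiole and 4 higher in leaf of 27 (median 0.88, camera adjusted p = 0.25). HD-ZIP factors had 31 and 20 of 74 (median 0.25, camera adjusted p = 0.334). YABBY and growth-regulating factors had 7 and 5 of 20, with a median of 0.02, a mean of -0.13 and a camera adjusted p of 0.841. BraA06g005620.3C, a YABBY2 locus, was lower in petiole at 25.7 ± 3.32 CPM against 39.8 ± 0.718 CPM in leaf, but its log2 fold change was 0.09 with limma on the deposited FPKM against a main value of -0.63. Another YABBY2 locus, BraA08g033150.3C, went the other way, at 24.1 ± 1.66 CPM in petiole against 12.2 ± 0.611 CPM in leaf (edgeR adjusted p = 3.87e-06). TCP, bHLH and LOB genes are also named in the series text. When adjusted over the list alone, 6 YABBY and growth-regulating loci were higher in petiole, and the other counts were as above.

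Of 85 cell cycle and DNA replication loci, 62 were higher in petiole and 5 higher in leaf (median 1.44, camera adjusted p = 2.44e-08, adjusted p = 0.042 with an estimated correlation). The B-type cyclin-dependent kinases CDKB1-1 (BraA04g005640.3C), which act at entry into mitosis, had 1.21 ± 0.236 CPM in leaf and 9.43 ± 0.952 CPM in petiole, and CDKB2-1 (BraA07g040180.3C) had 1.75 ± 0.449 and 9.37 ± 0.538 CPM. Core histones had 21 loci higher in petiole and 10 higher in leaf of 45 and did not pass (median 0.59, camera adjusted p = 0.096), except with limma without a filter (0.045). Cytosolic ribosomal proteins were higher in petiole for 213 of 262 loci and higher in leaf for 7, by a smaller and more even amount (median 0.59, SD over loci 0.47, camera adjusted p = 4.5e-13, adjusted p = 0.1 with an estimated correlation). Among cell cycle loci with a mean FPKM of at least 5, limma on the deposited FPKM no longer passed the list (camera adjusted p = 0.13, median 1.17). Higher in petiole when adjusted over the list alone were 63 cell cycle loci and 214 ribosomal protein loci.

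Among hormone and defence lists, jasmonate genes had the largest median. Jasmonate biosynthesis enzymes and JAZ repressors were higher in petiole for 44 of 57 loci and higher in leaf for 5 (median 2.35, or 2.33 with loci absent from a tissue set at their bound, camera adjusted p = 7.23e-10, adjusted p = 0.015 with an estimated correlation). The JAZ-type locus BraA06g013190.3C, annotated as TIFY 11A-like, had 0.0877 ± 0.0772 CPM in leaf and 19.9 ± 2.23 CPM in petiole, a log2 fold change of 7.83 ± 0.51 (SE) with an edgeR adjusted p of 1.58e-05. Glucosinolate biosynthesis genes, which make the sulphur-rich defence compounds of cabbages, were higher in petiole for 19 of 25 loci and higher in leaf for 4 (median 1.97, or 1.95 with bounds, camera adjusted p = 0.000146, adjusted p = 0.044 with an estimated correlation). BraA01g000830.3C, annotated as CYP79B2, the entry enzyme to indole glucosinolates, had 10.1 ± 1.66 CPM in leaf and 212.6 ± 12.1 CPM in petiole. Myrosinases and associated proteins, which act on glucosinolates after damage, had 6 loci higher in petiole and 2 higher in leaf of 10 and did not pass (median 1.01, camera adjusted p = 0.334). Auxin response and transport genes were higher in petiole for 91 of 186 loci and higher in leaf for 40 (median 0.79, camera adjusted p = 0.00775, adjusted p = 0.068 with an estimated correlation). The SAUR21-like locus BraA03g008300.3C of this list had 0.0437 ± 0.0674 CPM in leaf and 4.60 ± 0.949 CPM in petiole. Senescence-associated genes were higher in petiole for 7 of 10 loci and higher in leaf for 1 (median 1.30, camera adjusted p = 0.036, adjusted p = 0.16 with an estimated correlation). The senescence call was lost without leaf replicate 2 and without petiole replicate 1, 2 or 3 (camera adjusted p = 0.23, 0.094, 0.12 and 0.11, medians between 0.90 and 1.01), and both the auxin and senescence calls were lost on the deposited FPKM (camera adjusted p = 0.063 and 0.07). Over all alternatives these p ranged from 0.00058 to 0.27 for auxin and from 0.027 to 0.23 for senescence, which was also lost with DESeq2 (0.11). On list members with a mean FPKM of at least 5 there, the glucosinolate list no longer passed (camera adjusted p = 0.3).

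The other hormone lists went both ways and did not pass. Ethylene genes had 77 loci higher in petiole and 47 higher in leaf of 177 (median 0.45, camera adjusted p = 0.126). In that list, the ACC synthase 8 locus BraA01g001220.3C, of the committed step of ethylene synthesis, had 40.9 ± 2.6 CPM in leaf and 0.269 ± 0.234 CPM in petiole, while the ACC oxidase 1 locus BraA09g056530.3C had 0.170 ± 0.0583 and 17.3 ± 1.6 CPM. Gibberellin genes had 17 and 8 of 35 (median 0.55, camera adjusted p = 0.171). Cytokinin genes had 21 and 13 of 45 (median 0.64, camera adjusted p = 0.0977), with the response regulator ARR7 locus BraA08g028390.3C at 16.6 ± 0.844 CPM in leaf and 95.7 ± 3.52 CPM in petiole. Abscisic acid genes had 9 higher in petiole and 19 higher in leaf of 40 (median -0.49, camera adjusted p = 0.0584), close to the threshold. This list passed without leaf replicate 1 and without petiole replicate 1 or 3 (camera adjusted p = 0.038, 0.039 and 0.042), with DESeq2 (0.049), on the deposited FPKM (0.047, or 0.039 at a mean FPKM of at least 5) and on FPKM rescaled to a common total (0.04), by median-of-ratios (0.048) and by quantiles (0.042). The range over all alternatives was 0.038 to 0.11. Brassinosteroid genes had 8 and 15 of 27 (median -0.49, camera adjusted p = 0.179), with the CYP85A2 locus BraA02g039080.3C, of the last steps of brassinosteroid synthesis, at 38.99 ± 2.84 CPM in leaf and 2.06 ± 0.0526 CPM in petiole. Hormone synthesis genes are named in the series text as well. Adjusted over the list alone, the ethylene list had 81 loci higher in petiole and 49 higher in leaf, jasmonate had 45 higher in petiole, auxin had 93 higher in petiole, gibberellin had 9 higher in leaf and myrosinases had 3 higher in leaf.

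Guard cell and stomatal lineage markers had 6 loci higher in petiole and 10 higher in leaf of 21 (median -0.73, camera adjusted p = 0.205). With limma without a filter this list passed (camera adjusted p = 0.0065), and with DESeq2 the median of the guard cell and stomatal lineage markers was -1.67 (0.12). The TOO MANY MOUTHS locus BraA07g025640.3C, a receptor of stomatal patterning, had 16.1 ± 0.904 CPM in leaf and 0.639 ± 0.448 CPM in petiole. Epidermal wax and cutin genes had 11 and 20 of 38 (median -0.63, camera adjusted p = 0.133). The ECERIFERUM 3-like locus BraA03g012220.3C, of wax alkane synthesis, had 72.0 ± 1.19 CPM in leaf and 0.0848 ± 0.147 CPM in petiole. Pathogenesis-related proteins had 18 and 24 of 54 (median -0.40, camera adjusted p = 0.263). Nitrate and potassium transporters had 23 and 41 of 90 (median -0.41, camera adjusted p = 0.096), starch genes 16 and 20 of 41 (median -0.24, camera adjusted p = 0.523), flavonoid enzymes 6 and 7 of 17 (median -0.21, camera adjusted p = 0.893) and heat shock proteins 16 and 21 of 56 (median -0.37, camera adjusted p = 0.615). On the deposited FPKM the wax and pathogenesis-related lists passed as lower in petiole relative to other loci (camera adjusted p = 0.029 and 0.0043). There, 11 lists with a negative median on the counts had a median between 0.02 and 0.51, each below the 0.56 of all loci, and the heat shock median was 0.24 with DESeq2. Adjusted over the list alone, the wax list had 12 loci higher in petiole, the transporter list 24 and 42 higher in petiole and leaf and the heat shock list 17 higher in petiole.

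BraA08g003830.3C, MSTRG.21867 and BraA06g003700.3C had the highest mean FPKM in both tissues, and the deposited table gives none of them a functional description. BraA08g003830.3C stood at 30970 ± 5450 CPM in leaf and 11680 ± 58.2 CPM in petiole (log2 fold change -1.41 ± 0.144, SE). BraA06g003700.3C was higher in petiole (0.78 ± 0.114, SE, edgeR adjusted p = 0.00224), and MSTRG.21867 did not pass (0.20 ± 0.116, SE, edgeR adjusted p = 0.214), though it was higher in petiole with limma on the deposited FPKM (log2 fold change 0.94). The pair of loci with the most counts, annotated as a photosystem II CP43 protein and an ATP synthase subunit, lay over each other on chromosome A06 between 15079018 and 15619492 and merged several annotated genes. Together they took 20.9% ± 3.9 of the counts in leaf and 3.77% ± 0.06 in petiole (SD, n = 3 each). Without the loci of this region and without merged loci, 19191 of 30672 loci differed, 9616 higher in petiole and 9575 higher in leaf.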

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

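The tests of the FPKM denominator and of library scaling for the cell cycle and jasmonate lists were chosen after their outcome was in view. The tests of meristem and wound genes were chosen after the cell cycle and jasmonate results were seen but before their own values were, and the loci named in this part were singled out after their values were seen.

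The FPKM denominators held fragments that the table's loci did not hold. Under the assumption that the loci with the most units per FPKM and base of span are unspliced, 35.3% ± 1.87 of the leaf denominator and 12.8% ± 1.5 of the petiole denominator (SD, n = 3 each) lay outside the table, against about 0 if the table were complete. The plant carries organelle genomes that the chromosomes A01 to A10 do not include, so no loci of those genomes were analysed here. Whether some of their reads were counted at the plastid-like loci of chromosome A06, which stayed in the main test, was not tested. The larger share lay in leaf, the tissue with 20.9% of its counts on a pair of plastid-like loci against 3.77% in petiole, and what the fragments outside the table were stays open.

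A first pattern was the surplus of loci higher in petiole on the deposited FPKM, at 79.4% of the loci that differed against 50.3% on the counts. With the sum of the table as the denominator of each library and no centring, 64.9% were higher in petiole, with a median of all loci of 0.24 against 0.56, and with FPKM rescaled to a common total, which does not centre that median either, 54.0% were, with a median of 0.06. How much of the surplus went with the denominator thus depended on the total put in its place, from part to most of it. FPKM were proportional to the counts within each locus, so apart from pseudocount and filter they differed by a scale per library. The sum of the table itself includes the plastid-like region of chromosome A06. That region took 22.2% ± 3.87 of the counts in leaf and 4.0% ± 0.1 in petiole (SD, n = 3 each). Which scale matches the RNA of the tissues stays open. Median-of-ratios rescaling was first planned as this test, but it sets the middle of all loci near 0 whatever the source, so its 50.8% decides nothing. A true difference in RNA per cell between the tissues stays open and untested.

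A further pattern was the cell cycle list, higher in petiole. The lowest median of the list over 8 scalings was 0.68, reached where the median of all loci had been brought near 0. The main test also had a median of all loci near 0, at 0.01, but a list median of 1.44, so that centring alone does not give the 0.68. These medians do not decide on library scaling, since none of the scalings moved the middle of all loci toward leaf. A list already above the other loci could hardly change sign there. Meristem or flower tissue carried along with the petiole samples would need its own identity genes there. Of 54 such loci, 14 passed the filter on low counts and were tested, and the rest were too low to test. Of the 14 tested, 2 were higher in petiole at 1 CPM or more while 5 were higher in leaf. This met the outcome set beforehand as speaking against that tissue, and the verdict was changed after the value was seen, because only 6 of the 14 loci reached 1 CPM in either tissue and most of the list were CLE peptides, which other tissues also make. Meristem tissue therefore cannot be told apart from a difference between the organs, which stays an untested explanation.

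Another pattern was the jasmonate list, higher in petiole. Its lowest median over 8 scalings was 1.68. None of the scalings moved the middle of all loci toward leaf, so a list already above the other loci could hardly change sign. This test therefore does not decide on scaling. A wound or touch response at harvest would raise early response factors together. Of 53 such loci, 26 were higher in petiole and 13 higher in leaf, with a median of 0.36 (camera adjusted p = 0.0648), where 52 were expressed at 1 CPM or more and 14 also belong to the ethylene list. The WRKY40 locus BraA02g025510.3C, the most abundant of them in petiole, had 213.0 CPM in leaf and 471.6 CPM in petiole. The WRKY33 locus BraA03g020140.3C, the most abundant in leaf, had 232.7 and 182.3 CPM, and the ZAT10-like locus BraA09g036900.3C had 147.7 and 27.5 CPM. Other WRKY33 loci differed from the first, with BraA05g007160.3C higher in petiole (10.5 CPM in leaf, 51.8 CPM in petiole). BraA04g027230.3C did not pass (82.3 and 86.1 CPM). The largest changes of the list were toward petiole. Among them, the CML39 locus BraA07g040250.3C had no counts in leaf and 9.11 CPM in petiole. The ERF13-like locus BraA04g030920.3C had 0.933 CPM in leaf and 40.6 CPM in petiole. The strongest of the 13 changes toward leaf was a log2 fold change of -2.57 (ERF104 locus BraA03g044630.3C). With loci that go both ways, wounding cannot be told apart from a standing difference between the organs.

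With 6 libraries there are 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 19711 loci and the highest of the others gave 0, and 1 of the 10, the real one, gave as many. Each of the other splits put libraries of both tissues into each group. The tissue difference then widened the spread within groups, so their 0 decides nothing.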

How the results depend on the processing

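The number of loci that differed, 19711 in the main test, stayed close with DESeq2 (20460), with DESeq2 size factors in edgeR (19742), without a filter (19673) and, chosen after seeing the data, with counts divided by 3.78 (19932), overlapping loci summed (19682) and the plastid-like region and merged loci left out (19191). Leaving out each library in turn gave 18540 to 18899 loci, 9160 to 9612 higher in petiole, 9138 to 9498 higher in leaf, 10591 to 10767 at least 2-fold and 21 to 23 lists. With limma on log2(FPKM + 1) as deposited, 17271 loci were higher in petiole and 4485 in leaf. Pseudocounts of 0.1 and 0.5 gave 17201 and 4442, and 17263 and 4482. No filter gave 18431 and 5083, no trend or robust fitting gave 17301 and 4467. A mean FPKM of at least 5 gave 12162 loci in all, 2155 higher in leaf and 5870 at least 2-fold, with fewer loci tested. At least 2-fold loci numbered 6892 after median-of-ratios and 6867 after quantile rescaling of the FPKM, both with a pseudocount of 1. On the deposited FPKM the pseudocount mattered, with 9580 such loci at 1, 11472 at 0.5 and 12955 at 0.1. Other pseudocounts were not tested after rescaling. The log2 fold change of BraA06g005620.3C was above 0 with limma on the deposited FPKM, at 0.09, and 0.10 with either other pseudocount, 0.09 without a filter, 0.09 at a mean FPKM of at least 5 and 0.09 without trend or robust fitting. The shift of 0.56 of all loci on that scale exceeds its distance from 0. Lists that passed numbered 22 with camera, 12 with an estimated correlation and 40 with fry, which asks another question. Among single loci and lists, 4728 values kept direction and side of the threshold, 39 no longer passed and 33 newly passed, the cause was not tested. A further 6 were reversed. The 11 lists whose median changed sign on the deposited FPKM were not counted as reversed. Most of these single loci had been picked for a large change in the main test. Of all 19711 loci that differed there, 69.1% still passed with the same sign on the deposited FPKM. At a mean FPKM of at least 5, where fewer loci were tested, 39.5% did. With the replicate number as a block, 18683 loci differed (9338 higher in petiole, 9345 in leaf, 10252 at least 2-fold) and 22 lists passed. Deviations of same-numbered libraries correlated at -0.01 to 0.01, so the numbers were not taken as pairs. Depth limits loci near 12 units per library.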

Other observations

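The clock and pathway tests of this part were chosen after seeing the main results. Among KEGG pathways, 126 were tested for loci at least 2-fold higher in either tissue, and 22 passed in each direction at a Benjamini-Hochberg adjusted p under 0.05 over both directions (hypergeometric test, where genes are not independent). Stilbenoid biosynthesis, amino sugar and nucleotide sugar metabolism and tryptophan metabolism passed in both directions. Phenylpropanoid biosynthesis, which shares genes with the lignin list, had 117 of 338 loci higher in petiole (34.6%, against 18.7% of all loci with a pathway, adjusted p = 1e-10), and alpha-linolenic acid metabolism, which shares genes with the jasmonate list, had 41 of 101 (adjusted p = 6.3e-06). Linoleic acid metabolism had 15 of 28 (adjusted p = 0.00061). Starch and sucrose metabolism had 233 of 829 higher in petiole (28.1%, adjusted p = 2.9e-10) and 134 higher in leaf, whereas the fixed starch list of 41 loci did not pass and had a median of -0.24. Likewise, the fixed brassinosteroid and flavonoid lists did not pass, while brassinosteroid biosynthesis had 15 of 47 higher in leaf (adjusted p = 0.044), anthocyanin biosynthesis 13 of 23 higher in leaf (adjusted p = 0.00032) and flavonoid biosynthesis 32 of 103 higher in petiole (adjusted p = 0.012). In the other direction, the fixed cell cycle and DNA replication list passed, but the DNA replication pathway did not. It had 49 of 201 loci higher in petiole (24.4%, adjusted p = 0.11) and 33 higher in leaf. Carotenoid biosynthesis, which makes the accessory pigments of photosynthesis, had 25 of 72 loci higher in leaf (34.7%, against 16.7% of all loci with a pathway, adjusted p = 0.0018). The ubiquinone and terpenoid-quinone pathway, which includes plastoquinone and vitamin E, had 32 of 91 higher in leaf (adjusted p = 0.0003), and zeatin biosynthesis had 20 of 49 (adjusted p = 0.00078), whereas the fixed cytokinin list did not pass and had a median of 0.64.

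Circadian clock genes were mostly lower in petiole. Of 28 loci, 15 were higher in leaf and 4 higher in petiole (median log2 fold change -0.48, camera adjusted p = 0.0357 over 3 marker lists, adjusted p = 0.26 with an estimated correlation). The following loci were singled out after their values were seen. The pseudo-response regulator APRR1 locus BraA09g006930.3C, a core clock component, had 74.8 CPM in leaf and 19.01 CPM in petiole, and the GIGANTEA locus BraA09g040290.3C had 347.8 and 259.6 CPM. The REVEILLE 2 locus BraA05g015000.3C went the other way, with 0.596 CPM in leaf and 4.96 CPM in petiole. The time of day of sampling is not given in the labels.

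A set of 21 of 16669 loci with at least 1000 units in some library were at 0 in a replicate and at 1000 units or more in another replicate of the same tissue. Of these 17 (81.0%) overlapped another locus, against 12.9% of the others (Fisher's exact test, two-sided, p = 2.83e-12). Some of the 21 were both members of the same overlapping pair, so the loci were not independent and this p-value is too small. Singled out after their values were seen, MSTRG.22533 and MSTRG.22534 cover the same bases of chromosome A08 (12189028 to 12190535) on opposite strands. The first had 12222, 0 and 0 units in petiole replicates 1, 2 and 3, and the second had 0, 11340 and 799. In leaf both held near-equal units, with 9232 and 9228 in replicate 1, 10340 each in replicate 2 and 9265 each in replicate 3.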
